A study of Mus musculus with 2 samples.

How the data were processed

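Acetylation of lysine 27 on histone H3 (H3K27ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in hindbrain of mouse embryos at day 10.5. The series holds 1 group of 2 biological replicates. Replicate 1 pooled tissue of 69 embryos and replicate 2 tissue of 51 embryos, of both sexes per the labels. No other tissue, age or genotype belongs to the group, so no condition was compared with another.

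The 4 lists used were 1 peak list per replicate, 1 list from the pooled reads, and the replicated peaks. Per the file list that the authors deposited beside the peaks, each replicate's peaks were called on its own filtered alignments against a control. The pooled list was called on both replicates' alignments together, and all lists are in narrowPeak format on mm10. The replicated list was derived from the pooled list and both replicates' lists. The peak caller, its version and the rule that made a peak replicated are not given in the sources used here. The fold enrichment of each peak over the control is the authors' own deposited ratio. It served to describe, rank and filter peaks, and was not rescaled between lists. The authors also deposited a −log10 p-value and a −log10 q-value for each peak. The lowest −log10 p was 2.02 in replicate 1 and 2.00 in replicate 2, so the lists hold peaks with p up to 0.01 and include many weak ones. Depth is unknown, because peak lists give no read counts, and a missing peak shows only that no peak passed the authors' threshold, not that the mark was absent. Read alignments and signal tracks were not analysed here.

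Gene positions came from GENCODE release M21 on GRCm38, which is the mm10 build, and the 21938 protein-coding genes on the assembled chromosomes were used. Coordinates are 1-based. A promoter was the 1000 bp on either side of any annotated transcription start site (TSS) of a gene, and a gene's promoter fold was the highest fold among the peaks there. A peak that only partly reached into a promoter counted there with its whole fold. Each peak was put in 1 class, in the order promoter, gene body, intergenic. A distal peak was a replicated peak over 1000 bp from every protein-coding TSS, and it was counted for each gene whose 5′ end lay within 100000 bp. Domains were replicated peaks joined over gaps of up to 3000 bp. They were ranked by acetylated length, the summed width of their peaks, and the top 5% were called top domains.

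Replicates were compared by the share of peaks that overlapped a peak of the other replicate by at least 50% of their own length. The same share was computed after 100 shuffles of peak positions within chromosomes. Exact binomial (Clopper-Pearson) intervals at 95% are given for shares of peaks or genes, and cover counting error only. A set of 22 gene lists, written from general knowledge of embryonic tissues, were tested for promoter peaks with a two-sided Fisher's exact test against all other protein-coding genes. The same test compared top domains between a list's genes with a promoter peak and all other such genes, for the 18 lists with at least 5 such genes. Mean numbers of distal peaks were compared with 10000 random lists of the same size by a two-sided resampling test. Random genes were drawn with replacement, matched on deciles of the number of other protein-coding genes' 5′ ends within 100000 bp. P-values were adjusted over the lists by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. Genes or regions are the units of these tests, so the p-values describe these peak lists and do not measure the spread between embryos. Neighbouring genes can share peaks, as within a Hox cluster, and are not independent. A total of 5 genes belong to more than 1 list, among them 4 of the roof plate list. The listed symbol Tf was not among the protein-coding genes and was left out.

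The lists, windows, tests, alternatives and the rule for named genes were fixed before the data were examined. Named genes were, for each list, the 2 members with the highest pooled fold in a replicated promoter peak and the first 2 in list order without one, besides any Hox gene. Named regions were the 10 longest domains, the 10 distal peaks with the highest fold (no more than 1 per nearest gene) and the 5 strongest peaks seen in each replicate alone. The 10 genes outside the lists with the most distal peaks, at least 200000 bp apart, were also named. Genes of families and non-coding genes named among the other observations fall outside this rule and were chosen after their values were seen.

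Alternatives changed the overlap rule, the promoter window, the start sites used, the peak list or its threshold, the background genes, the reach and matching of the distal test, and the joining and ranking of domains. Each replicate was also left out in turn by using the other replicate's own peak list. A pair of alternatives was chosen after seeing the data: replicated peaks that overlap a peak in both replicates' lists, and random gene lists matched on deciles of promoter CpG content (observed over expected CpG around the 5′ end). Their effects are given in the closing section, and in the results where they end a call.

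The methods were tested on simulated data. With 200 genes in 10 lists given wide promoter peaks and added distal peaks among 21938 genes, the promoter, distal and domain tests each recovered 10 of 10 lists, and called 0 of 10 unchanged lists. The planted effects were large, the unchanged lists were random genes, and simulated peaks did not depend on CpG content. The simulation therefore does not show how often real lists would be missed or falsely called. For the replicate overlap, 50.0% of 81551 simulated peaks were shared and 50.0% were found. The domain test failed in an earlier simulation whose peaks had equal widths: ties at the threshold placed 97.0% of genes with a promoter peak in top domains and 0 of 10 lists were recovered. The deposited peaks gave 2448 top domains of 48958, and such ties did not arise. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.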

Results

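H3K27ac was mapped in hindbrain at embryonic day 10.5, when the segmented hindbrain is producing neurons, in 2 pools of embryos. Replicate 1 gave 170712 peaks that covered 84.5 Mb, with a median width of 267 bp and a median fold enrichment of 2.91. Replicate 2 gave 141299 peaks over 85.9 Mb, with a median width of 330 bp and a median fold of 3.17. The authors' list of replicated peaks held 96312 regions, 85.8 Mb or 3.15% of the assembled chromosomes. Its median fold was 3.34 and its highest 52.3. In replicate 1, 23.0% of peaks had a q-value above 0.01, and in replicate 2 15.5%.

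The first comparison asked how far both pools of embryos marked the same regions. The strongest regions were shared: when each replicate's peaks were split into 4 equal groups by p-value, 87.1% of replicate 1 peaks and 84.0% of replicate 2 peaks in the strongest group overlapped the other replicate. In the weakest group the shares were 25.1% and 25.6%. Over all peaks, 48.5% of replicate 1 peaks (95% interval 48.3 to 48.8) and 47.9% of replicate 2 peaks (47.6 to 48.2) were shared, against 3.30% and 3.03% after shuffling. Across the 82547 replicated peaks with a peak in both lists, the replicates' folds had a Spearman correlation of 0.727 and, on the log2 scale, a Pearson correlation of 0.908. These correlations are across regions, which are not independent replicates. Another 13765 replicated peaks (14.3%) lacked a peak in at least 1 replicate's own list, and their median pooled fold was 2.76, against 3.49 for those with both.

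Peaks seen in only 1 replicate's list had a median fold of 2.72 in replicate 1 and 2.82 in replicate 2, against 2.91 and 3.17 over all peaks of each list. The 5 strongest of each exceeded 4.64, the upper quartile of fold among the replicated peaks. The strongest of the 70327 peaks seen only in replicate 1 lay 69.3 kb from the start of Irf2bp2, a transcriptional corepressor gene, on chromosome 8 from 126663267 to 126664183, with a fold of 6.27. The next were intergenic peaks nearest Sdk2 (5.67), Mef2d (5.63) and Gm11146 (5.27), and a peak in an intron of Sema6d (5.27). The strongest of the 49918 peaks seen only in replicate 2 lay 31.1 kb from Syt13, a synaptotagmin gene, on chromosome 2 from 92883249 to 92883959, with a fold of 8.34. It was followed by an intergenic peak nearest Rapgef2 (7.09), a peak in an untranslated region of Plod1 (6.73), and intronic peaks of Cobll1 (6.67) and Anks1b (6.46). All 10 of these regions were also in the pooled list. The overlap share depended on how peaks were selected: at a −log10 q of at least 5 it was 72.7% for replicate 1 and 65.5% for replicate 2.

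**Figure D1:**
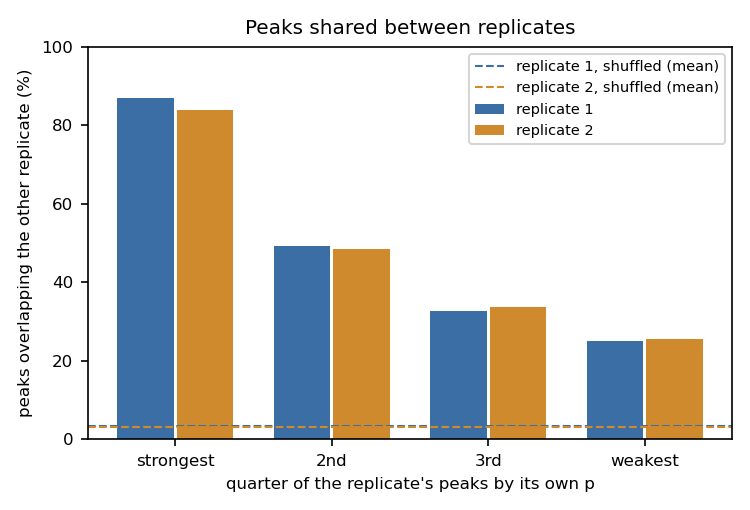
Percent of each replicate's peaks that overlapped a peak of the other by at least 50% of their own length, for 4 equal groups of the replicate's peaks ranked by p-value. Bars fall from 87.1% and 84.0% in the strongest group to 25.1% and 25.6% in the weakest, and dashed lines mark the mean after shuffling, 3.30% and 3.03%.

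The next description concerned where the mark lay. Promoters of protein-coding genes, 3.59% of the assembled chromosomes, held 21.2% of replicated peaks (95% interval 20.9 to 21.4), and these promoter peaks had a median fold of 8.21. Gene bodies held 42.3% of the peaks on 35.2% of the chromosomes, with a median fold of 3.11, and intergenic sequence held 36.5% on 61.2%, with a median fold of 3.22. Strength separated promoters from the rest: 86.6% of the top 10% of peaks by fold were at promoters and 96.4% of the top 1%, but 8.87% of the lowest 50%. With a promoter window of 2500 bp the promoter share was 26.8%.

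The central comparison asked which groups of genes carried the mark at their promoters. Of 21938 protein-coding genes, 14795 (67.4%) had a replicated promoter peak, and the median of their highest folds was 14.3. Replicate 1 alone marked 15096 genes and replicate 2 alone 15226. Genes of neural progenitors, of neurogenesis and of young neurons were acetylated without exception, while Hox genes of groups 5 to 13 had no replicated promoter peak and olfactory receptors almost none. Of 22 lists, 10 had more acetylated promoters than other genes, 6 had fewer and 6 were not called.

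The Hox genes, which give hindbrain and trunk segments their identity, split by position in their clusters. A replicated promoter peak was present at 11 of the 12 genes of paralogue groups 1 to 4, at 0 of 11 genes of groups 5 to 8 and at 0 of 16 genes of groups 9 to 13. Hoxa1 and Hoxa2, at 52155590 to 52158317 and 52162417 to 52164831 on chromosome 6, shared 1 peak with a pooled fold of 19.7 (14.9 in replicate 1 and 23.6 in replicate 2). Hoxb2, on chromosome 11 from 96350525 to 96354012, reached 19.5 (16.1 and 21.7), Hoxb3 8.74 (9.81 and 10.1) and Hoxd3 8.17 (8.72 and 7.29). Weaker peaks marked Hoxb1 at 4.99, Hoxa4 and Hoxb4 at 4.26, Hoxd4 at 4.10, Hoxc4 at 3.57 and Hoxa3 at 2.88. Hoxc4 had no peak in replicate 2. Hoxd1 had a weak peak in each replicate (2.33 and 2.501) that was not among the replicated ones. In groups 5 to 8, single replicates gave weak peaks at Hoxa5 (3.09), Hoxb5 (2.56), Hoxb8 (2.36) and Hoxc5 (2.54) in replicate 1 and at Hoxd8 (3.13) in replicate 2. In groups 9 to 13, replicate 2 gave weak peaks at Hoxa13 (2.34) and Hoxd11 (2.71). By Fisher's exact test the adjusted p was 0.138 for groups 1 to 4, 3.18e-05 for groups 5 to 8 and 1.74e-07 for groups 9 to 13. The call for groups 5 to 8 was lost without replicate 2 (36.4% of genes, adjusted p 0.0678). Groups 1 to 4 gained a call in that setting (0.0469) and with all pooled peaks (0.0374), but with each gene's 5′ end only they lay below other genes (58.3% against 63.7%, 0.803).

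**Figure D2:**
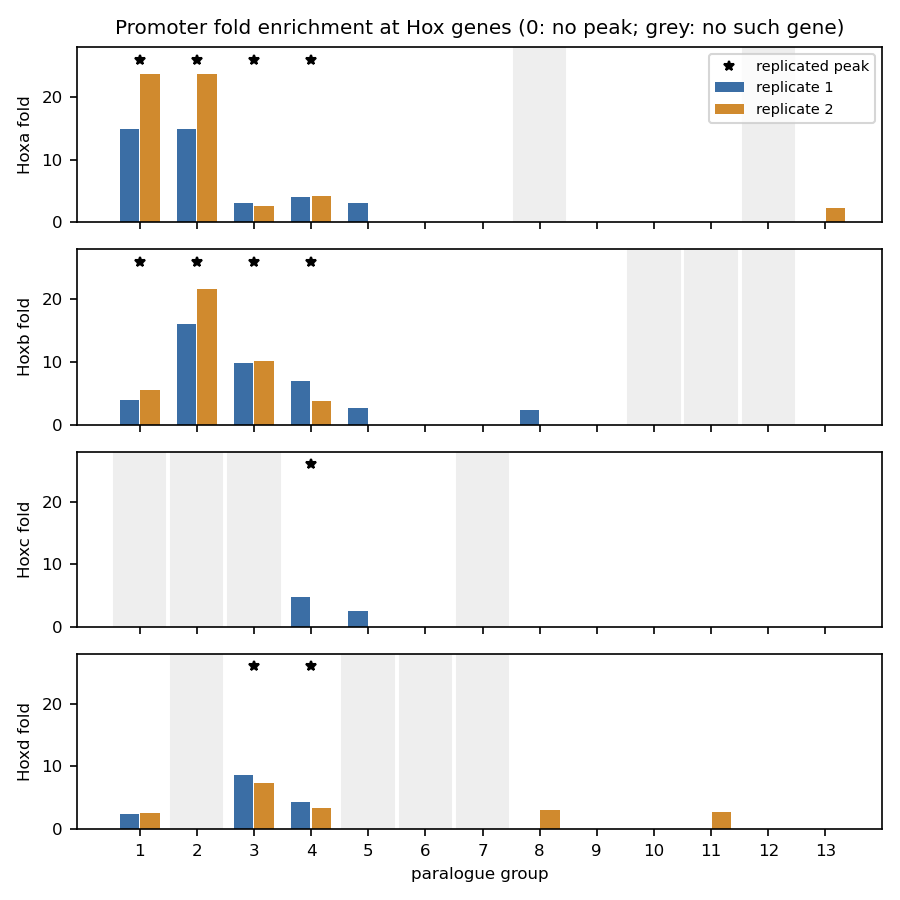
Highest promoter fold enrichment at each Hox gene in replicate 1 (blue) and replicate 2 (orange), by paralogue group, with 1 panel per cluster and stars for replicated peaks. The highest bars are at Hoxa1 and Hoxa2 (14.9 and 23.6) and Hoxb2 (16.1 and 21.7), and genes of groups 5 to 13 have no star.

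Genes of the neural lineage were marked from progenitor to neuron. All 24 neural progenitor genes had a promoter peak (adjusted p 0.000452), led by Msi1, an RNA-binding protein of neural stem cells, at a pooled fold of 41.2 (32.6 and 49.1) and Id3, an inhibitor of differentiation, at 36.8 (27.2 and 21.3). The pooled fold of Id3 exceeded both of its replicate folds. In replicate 2 several other progenitor genes were higher, among them Prom1 (34.6), Hes1 (31.7) and Sox2 (30.6). All 20 genes of neurogenic commitment were marked (0.00172), with Hes6 at 23.6 (18.0 and 28.7) and Nhlh2 at 18.3 (16.3 and 17.5). All 18 genes of post-mitotic neurons were marked (0.00327), with the neuronal RNA-binding gene Elavl4 at 27.6 (18.2 and 36.1) and the axonal gene Dpysl3 at 18.8 (16.9 and 25.01). Each of these 3 lists kept its call in all 11 alternatives, with adjusted p from 5.83e-05 to 0.0248. They also exceeded random lists matched on promoter CpG content, of which on average 83.9%, 74.6% and 75.4% of genes were marked.

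Patterning genes of the hindbrain carried the mark at most promoters. Of 20 hindbrain and isthmus genes 19 were marked (adjusted p 0.0139), with the nuclear receptor gene Nr2f1 at 43.2 (34.3 and 47.7) and the Hox cofactor gene Meis1 at 38.4 (29.8 and 41.3). Hnf1b was the exception. Of 25 transcription factors of hindbrain neurons 22 were marked (0.0428), with Bhlhe22 at 10.1 (8.90 and 11.9) and Pax2 at 8.74 (7.18 and 6.50), while Mnx1 and Vsx2 had no peak in any list. Floor plate and ventral genes were marked at 15 of 16 (0.0428), with the Hedgehog receptor gene Ptch1 at 26.7 (24.7 and 30.2) and Nkx6-1 at 14.7 (11.1 and 16.9), and Arx was without a peak. Roof plate and dorsal genes were also marked at 15 of 16 (0.0428), with Zic4 at 21.9 (24.0 and 25.6) and Pax3 at 19.1 (15.4 and 21.6). Wnt8b had a peak of 4.51 in replicate 2 and none in replicate 1. Against random lists matched on promoter CpG content all 4 calls ended, since on average 91.5%, 84.6%, 90.4% and 92.1% of the matched genes were marked, and except for the neuron factors the matched range reached 100%, so that no higher share could have been shown. The hindbrain and isthmus call was also lost at a fold of at least 4 (adjusted p 0.0550 by Fisher's exact test). The other 3 were lost at that fold, without replicate 2, and when olfactory receptors were left out of the background genes. These 3 calls therefore depended on comparison with genes that include the olfactory receptors. Those of neuron factors and floor plate were also lost without replicate 1. The 3 calls held in 4 (neuron factors), 2 (floor plate) and 7 (roof plate) of 11 alternatives.

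Among lists of neighbouring tissues, of the retinoic acid pathway and of other brain regions, the crest and mesenchyme list alone was called. All 24 neural crest and cranial mesenchyme genes were marked (adjusted p 0.000452), led by the crest regulator Tfap2a at 13.8 (10.4 and 18.1) and Foxc1 at 13.01 (12.2 and 11.3), and matched lists averaged 72.9%. In the retinoic acid pathway, which patterns the hindbrain, 13 of 15 genes were marked (0.175), with the receptor cofactor gene Nrip1 at 31.1 (24.0 and 35.4) and Crabp2 at 23.0 (17.5 and 25.3), while Aldh1a1 and Rbp1 had none. Forebrain and midbrain genes were marked at 20 of 24 (0.139), with Lef1 at 17.0 (11.3 and 20.4) and Otx1 at 8.75 (6.90 and 10), but not Six6 or Tbr1. Surface ectoderm and otic genes were marked at 13 of 16 (0.295), with Eya4 at 21.9 (17.3 and 24.4) and Grhl2 at 20.6 (14.5 and 25.1), but not the epidermal genes Krt14 and Trp63. Endothelial genes were marked at 14 of 16 (0.135), with Fli1 at 13.1 (11.1 and 13.96) and Egfl7 at 12.8 (8.75 and 15.2), whereas Tek and Tie1 had only unreplicated peaks of 2.65 and 2.30. The crest call was lost at a fold of at least 4 (0.0550), the retinoic acid list gained a call against CpG-matched lists (62.1% expected, 0.0344), and endothelium gained one with all pooled peaks (0.0115). Without a call, forebrain (58.3%), surface ectoderm (56.2%) and endothelial genes (56.2%) lay below other genes (60.8%) at a fold of at least 4, as did endothelium with the 5′ end only (62.5% against 63.7%) and forebrain against CpG-matched lists (83.3% against 86.5%).

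Blood, muscle and liver genes were marked less often than other protein-coding genes, with calls that depended on the comparison. In blood and macrophages 7 of 18 genes had a promoter peak (adjusted p 0.0338), among them Klf1, an erythroid regulator, at 13.01 (10.4 and 13.96) and Runx1 at 8.40 (6.54 and 9.17), but not Gata1, and Gfi1b had only an unreplicated peak of 2.42. In muscle and heart 6 of 17 were marked (0.0143), with Myh7 at 5.29 (5.81 and 7.46) and Gata6 at 4.85 (3.45 and 6.88), while the muscle regulators Myod1 and Myf5 had only unreplicated peaks, of 2.43 in replicate 2 and 2.54 in replicate 1. In liver and gut 3 of 14 were marked (0.00172), with Foxa3 at 17.2 (13.99 and 20.01) and Vil1 at 3.09 (2.86 and 3.18), and the liver genes Alb and Apoa1 had no peak. Mature glial and adult neuronal genes were marked at 7 of 16 (0.0765), with Slc1a2 at 16.3 (11.99 and 19.6) and Mbp at 15.3 (6.96 and 20.6), but Plp1 had a peak only in replicate 2 (2.92) and Mog none. Of 1135 olfactory receptor genes 4 were marked, 0.352% (95% interval 0.0961 to 0.8999) against 71.1% of other genes, the strongest being Olfr94 at 4.83 and Olfr145 at 3.11, the latter without a peak in replicate 1. The calls for blood, muscle and liver ended against CpG-matched lists (30.5%, 55.5% and 43.9% expected) and with all pooled peaks, those for blood and muscle also without either replicate, and that for muscle with a window of 2500 bp. Blood genes then lay above their matched lists, and mature glial and neuronal genes gained a call in 5 of 11 alternatives (adjusted p 0.0294 to 0.795 over all 11).

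Genes that all dividing cells use were marked throughout. All 18 cell cycle genes had a promoter peak (adjusted p 0.00327), with Rrm2 at 31.7 (22.9 and 36.1) and Mki67 at 30.5 (21.6 and 35.6). All 18 housekeeping genes were marked too (0.00327), with Actb at 46.2 (30.8 and 47.8) and Ywhaz at 45.5 (38.3 and 48.6). Against CpG-matched lists both calls ended (93.9% and 89.1% expected, adjusted p 0.589 and 0.206), whose range reached 100%.

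**Figure D3:**
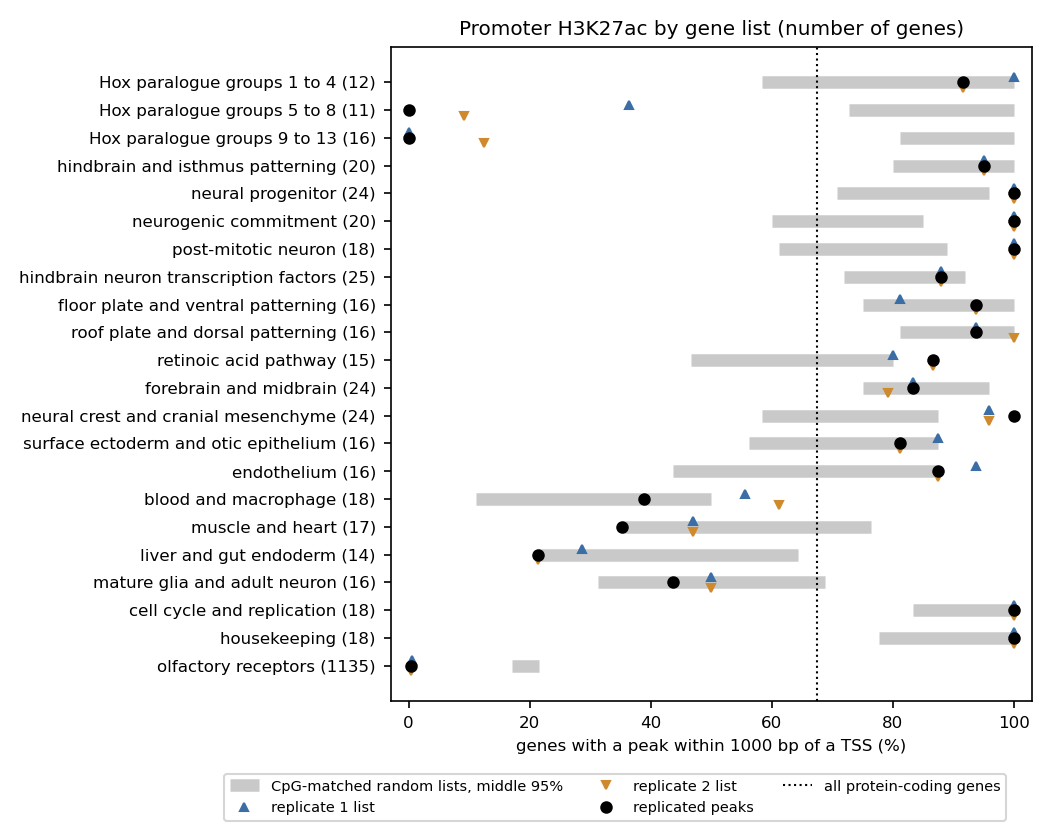
Percent of each gene list with a promoter peak among the replicated peaks (circles) and in each replicate's list (triangles), beside the middle 95% of random lists matched on promoter CpG content (grey) and the share of all protein-coding genes (dotted, 67.4%). Hox groups 5 to 8 and 9 to 13 lie at 0, and the progenitor, neurogenic, post-mitotic and crest lists at 100%, outside their grey ranges.

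A further comparison asked which genes had more distal peaks, the candidate enhancers, around them than genes in regions of like gene density. Neighbouring peaks were counted singly, so a broad domain can add many distal peaks to a gene. These counts are therefore not independent of the domain results below. Neural progenitor genes had the most, a mean of 23.1 (SD 16.4, n = 24 genes) within 100000 bp against 7.06 for matched random lists (adjusted p 0.00110). Neurogenic genes averaged 16.4 (SD 9.26) against 7.11 (0.0103), roof plate and dorsal genes 15.6 (SD 11.6) against 7.16 (0.0123), and hindbrain and isthmus genes 15.4 (SD 11.9) against 7.04 (0.0104). Transcription factors of hindbrain neurons averaged 13.6 (SD 14.5) against 7.16 (0.0165), and crest and mesenchyme genes 12.9 (SD 15.0) against 7.27 (0.0358). Olfactory receptors had 0.523 (SD 1.68) against 8.52 (0.00110). For the progenitor and olfactory lists the unadjusted p of 1e-04 by the resampling test was the smallest that 10000 draws allow. Over all protein-coding genes the mean was 7.47, from 75906 distal peaks, and 5611 genes had none.

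The Hox genes were not called, with means of 7 for groups 1 to 4, 5.09 for groups 5 to 8 and 3.94 for groups 9 to 13. Endothelial genes, at 12.8 against 7.25 (adjusted p 0.0729), surface ectoderm genes, at 12.4 against 7.40 (0.110), and 10 other lists were not called either. Groups 9 to 13 were called lower without replicate 1 (0.0334) and with peaks in both replicates (0.0456), and endothelium higher without either replicate (0.0334 and 0.0451) and within 50000 bp (0.0394). The surface ectoderm, mature glial, cell cycle and housekeeping lists were each called higher in 2 alternatives and the retinoic acid list in 1. When random lists were also matched on having a promoter peak, the progenitor, neurogenic and hindbrain and isthmus calls held, and those for hindbrain neuron factors (0.0559), roof plate (0.0524) and crest and mesenchyme (12.9 against 9.20, 0.246) did not. Without a call, Hox groups 5 to 8 (5.09 against 3.08) and 9 to 13 (3.94 against 3.22) then lay above their matched lists, as did groups 1 to 4 within 50000 bp (4.17 against 3.53).

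Outside the lists, Sulf2, which encodes a heparan sulfatase, had the most distal peaks, 94 within 100000 bp of its 5′ end on chromosome 2, followed by Tspan18 with 93. Ncor2 and Zmiz1, which encode transcriptional coregulators, had 83 each, Flrt1 81, Ccdc182 80, Hhipl1 and Tcp11 75 each, and Gm26897 and Parvg 74 each. All 10 genes had a replicated promoter peak, from 2.99 at Gm26897, which had none in replicate 2, to 33.8 at Zmiz1 (25.3 and 39.6).

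The strongest distal peaks lay mostly at starts of non-coding genes. The first, on chromosome 1 from 72243580 to 72244268, had a fold of 41.4 (29.1 and 47.7) and lay 31.3 kb from Mreg, within 1000 bp of a start of the non-coding gene D230017M19Rik. The next had a fold of 41.1 (31.2 and 45.8), on chromosome 1 from 86432423 to 86444856, 6.09 kb from Tex44. Further peaks lay at the non-coding genes 6720427I07Rik near A830005F24Rik (40.6), 1810026B05Rik near Chd2 (37.99), Malat1 near Scyl1 (37.99), Gm48623 near Cplx2 (37.8) and Mir17hg, host of a microRNA cluster, near Gpc5 (36.4). Others lay at a pair of small nuclear RNA genes near Sirt4 (37.1) and at 2310015A10Rik near Zfp36l1 (36.3). The peaks near Tex44 and near Chd7, the latter on chromosome 4 from 8909114 to 8915489 with a fold of 36.9 (28.5 and 40.0), had no annotated start of any gene within 1000 bp. All 10 were intergenic with respect to protein-coding genes.

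**Figure D4:**
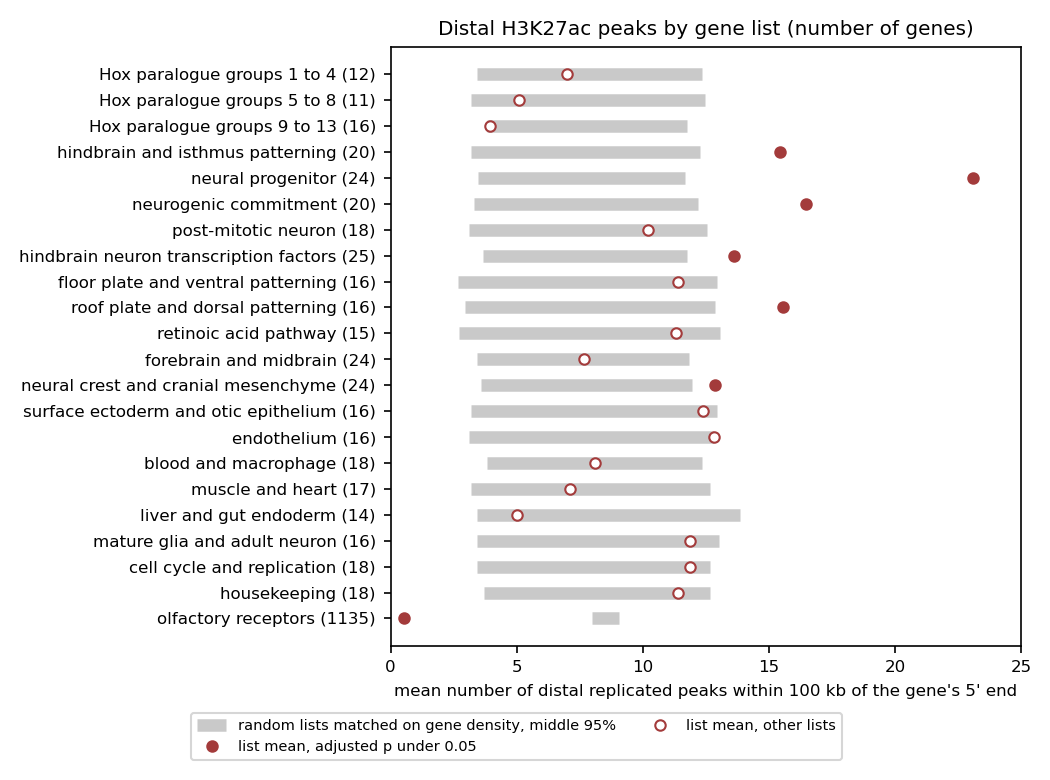
Mean number of distal replicated peaks within 100 kb of each list's genes (circles, filled where adjusted p was under 0.05) beside the middle 95% of 10000 random lists matched on gene density (grey). Neural progenitor genes average 23.1 and olfactory receptors 0.523.

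The last comparison concerned broad acetylated domains, long stretches of the mark that often surround genes of cell identity. Joining replicated peaks gave 48958 domains, of which 29757 were single peaks, and the 2448 top domains held at least 5266 bp of acetylated sequence. They covered promoters of 1618 genes, 10.9% of those with a promoter peak. Progenitor genes lay in them most often, at 21 of 24 or 87.5% (95% interval 67.6 to 97.3; adjusted p 1.53e-16). Neurogenic genes followed with 14 of 20 (6.12e-09), Hox groups 1 to 4 with 7 of 11 (0.000184) and hindbrain and isthmus genes with 12 of 19 (4.08e-07), by Fisher's exact test. The 7 Hox genes were Hoxa1, Hoxa2, Hoxb2, Hoxb3, Hoxb4, Hoxd3 and Hoxd4. Neighbours in a cluster can share a domain, so the test counts as separate some genes that are not independent.

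Floor plate and roof plate genes each had 7 of 15 marked genes in top domains (0.00138), retinoic acid genes 6 of 13 (0.00294), hindbrain neuron factors 9 of 22 (0.00104), crest and mesenchyme genes 9 of 24 (0.00139) and post-mitotic neuron genes 6 of 18 (0.0177), by Fisher's exact test. Forebrain and midbrain genes had 3 of 20, cell cycle genes 4 of 18, housekeeping genes 5 of 18 (0.0647), endothelial genes 4 of 14 (0.0874), surface ectoderm genes 1 of 13 and mature glial and neuronal genes 2 of 7, and none of these was called. Blood genes had 0 of 7 and muscle and heart genes 0 of 6, and no list was called lower. The hindbrain and isthmus and the progenitor calls held in all 10 alternatives, whereas 4 of the 10 lists lost theirs with single peaks (Hox groups 1 to 4, neuron factors, floor plate, crest), 6 with gaps of 12.5 kb (neurogenic, post-mitotic, neuron factors, floor plate, retinoic acid, crest), 5 with the top 1% (the same without retinoic acid), 6 with ranking by width times fold (post-mitotic, neuron factors, floor plate, roof plate, retinoic acid, crest), 3 at a fold of at least 4 (post-mitotic, neuron factors, crest), 1 with all pooled peaks (post-mitotic) and 1 without replicate 2 (floor plate, 30.8%, 0.166). Of these 26 losses 5 came with a change of direction, to below other genes: post-mitotic genes with gaps of 12.5 kb (16.7% against 17.4%) and the top 1% (0 against 2.92%), neuron factors with single peaks (13.6% against 18.6%) and with width times fold (9.09% against 17.3%), and crest genes with width times fold (12.5% against 17.3%). Housekeeping genes were called with single peaks (72.2%, 4.73e-06) and with ranking by width times fold (66.7%, 4.16e-05), but had 0 against 2.92% with the top 1%. Endothelial genes were called in 3 alternatives (0.0395 to 0.0452) and mature glial genes with all pooled peaks (0.0438), and the forebrain, surface ectoderm, endothelial, muscle, mature glial and cell cycle lists also changed direction in 1 or more alternatives, without a call.

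The longest domain held 142.678 kb of acetylated sequence in 67 peaks on chromosome 8, from 120249472 to 120432812, and lay 21.02 kb from the nearest start of Gse1, which encodes a coiled-coil protein. Another Gse1 domain, at its promoter, ranked among the first 4 with 92.0 kb from 120455175 to 120580474. The domain within Msi2, a relative of Msi1, held 127.8 kb on chromosome 11 from 88372633 to 88569597. Those near Mn1 on chromosome 5 and near Cstad on chromosome 2 held 107.1 kb and 89.9 kb. Domains at the promoters of Ccdc182 (89.3 kb), Ccdc85c (68.8 kb), Cep41, Cpa1 and Cpa5 (63.8 kb), Mrpl23 and Tnnt3 (57.7 kb), and Ano1 and Fadd (57.3 kb) completed the 10 longest. In the longest domain 66 of the 67 peaks overlapped a peak of replicate 1 and 64 a peak of replicate 2.

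**Figure D5:**
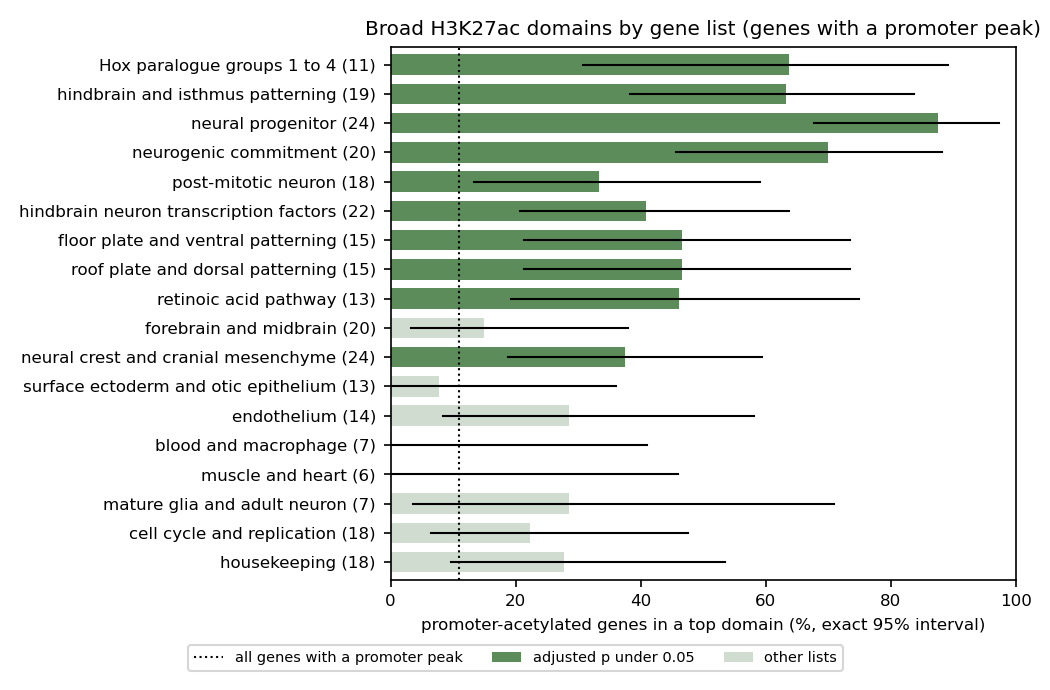
Percent of each list's genes with a promoter peak that lay in a top domain, with exact binomial 95% intervals, dark where adjusted p was under 0.05, and the share of all genes with a promoter peak (dotted, 10.9%). Neural progenitor genes reach 87.5%, and blood and muscle genes stay at 0.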

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

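No test was made of the values in this part, and no explanation was weighed for them. Signal outside the assembled chromosomes stood out because none of the genes used here lies there. There, 11 replicated peaks lay on 6 unplaced or unlocalised scaffolds, with pooled folds from 1.52 to 36.3. Scaffold peaks stayed in the replicate overlap, the total of distal peaks and the domains, and were left out of the genomic classes. The pooled list also held 98079 peaks that were not among the replicated ones, with a median fold of 2.42. Through these, 742 protein-coding genes (3.38%) had a promoter peak in the pooled list and none among the replicated peaks. The median promoter fold of these genes was 2.42 and the highest 3.56. Hoxd1 was one of them, at 2.76, as were the endothelial genes Tek at 2.65 and Tie1 at 2.30. With 1 group of 2 replicates no sample could be tested as an outlier and no effect could differ between groups.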

How the results depend on the processing

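Tests with CpG-matched random lists and with replicated peaks seen in both replicates' lists were chosen after the data were seen. CpG matching was applied to promoter peaks only, so the distal and domain calls were not tested against it. For promoters, 5 of 16 calls held in all 11 alternatives (progenitor, neurogenic and post-mitotic genes, Hox groups 9 to 13 and olfactory receptors). Of 242 pairs of list and alternative, 190 kept direction and side of the threshold, 36 kept direction but lost a call, 9 gained one and 7 changed direction, 1 of them with loss of a call (37 calls lost in all). For distal peaks 4 of 7 calls held throughout, and of 198 pairs 166 were kept, 3 kept direction but lost a call, 14 gained one and 15 changed direction, none of these called at first. For domains 2 of 10 held throughout (hindbrain and isthmus, and progenitor genes), and of 179 pairs 133 were kept, 21 kept direction but lost a call, 6 gained one and 19 changed direction, 5 of them with loss of a call (26 lost in all). Of 66 named genes, the presence of a promoter peak changed for 0 at a −log10 q of at least 5, for 2 at a fold of at least 4, for 7 with all pooled peaks, for 6 without replicate 1, for 5 without replicate 2, and for 1 with peaks in both replicates. The Spearman correlation of replicate folds stayed at 0.726 and 0.743 with stricter q.

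The overlap of replicate 1 (48.5%) became 58.8% with any overlap, 32.9% with 50% of both peaks, 53.2% and 72.7% at a −log10 q of at least 2 and 5, and 59.2% with equal numbers of peaks. That of replicate 2 (47.9%) became 64.7%, 39.7%, 48.6%, 65.5% and 49.9%. A looser or stricter overlap rule changes the share by its construction, and the cause was not tested for the others. The promoter share (21.2%) was 19.1% and 26.8% with windows of 500 and 2500 bp and 25.4% with all annotated genes, as wider or added promoters take in more peaks. It was 14.4% with all pooled peaks, where the cause was not tested.

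Lists with more promoter peaks fell from 10 to 5 at a fold of at least 4 and to 5 with CpG matching, with 4 of the latter among the original 10. Lists with fewer went from 6 to 3 with all pooled peaks and 3 with CpG matching, and were 3 to 4 with 1 replicate left out. Lists with more distal peaks rose from 6 to 10 within 50000 bp. Lists with fewer went from 1 to 2 with peaks in both replicates, and were 1 to 2 with 1 replicate left out. Lists enriched in top domains fell from 10 to 4 with gaps of 12.5 kb, 5 with the top 1% and 5 with ranking by width times fold. For these changes the cause was not tested.

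Changes of direction, all of them without a call under the alternative, were as follows, and the cause was not tested. For promoters these were Hox groups 1 to 4 (58.3%) and endothelium (62.5%) with the 5′ end only, forebrain (58.3%), surface ectoderm (56.2%) and endothelium (56.2%) at a fold of at least 4, and forebrain (83.3%) and blood (38.9%) with CpG matching. For distal peaks they were means of 14.7 for forebrain and 18.1 for muscle with all pooled peaks, 10.8 to 12.5 and 12.6 to 14.2 with 1 replicate left out, and 22.8 for muscle within 250000 bp. Within 50000 bp Hox groups 1 to 4 (4.17) and blood (3.39) changed, and at a fold of at least 4 blood (1.61). With matching on promoter peaks, the means of Hox groups 5 to 8 (5.09) and 9 to 13 (3.94), forebrain (7.67), muscle (7.12) and liver (5) changed side.

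For domains, gaps of 12.5 kb changed post-mitotic (16.7%), forebrain (0), surface ectoderm (30.8%) and muscle genes (33.3%). Single peaks changed hindbrain neuron factors (13.6%), forebrain (15%) and endothelium (7.14%). The top 1% changed post-mitotic, forebrain, mature glial, cell cycle and housekeeping genes (all 0) and surface ectoderm (7.69%). Ranking by width times fold changed hindbrain neuron factors (9.09%), forebrain and mature glial genes (both 0), crest (12.5%) and endothelium (7.14%), and a fold of at least 4 surface ectoderm (11.1%). Muscle and heart genes gave no domain value at a fold of at least 4, with under 5 genes left. Depth limits what the weak peaks show, and without read counts it could not be measured.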

Other observations

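Tests of gene density on the X chromosome, of CpG content for the gene lists and Hox genes, and of other tissues in the sample were chosen only after the result was seen. Those of CpG content and of copy number on the X chromosome were written before their values were seen. The prediction for a single active X copy was kept, but its verdict was changed to open afterwards. After their tests had run, the criterion for a general admixture of tissues was reworded, and that for CpG content of lists whose call ended was split. The gene families were defined after the data were examined and before their values as families were looked at. Members that also belong to the gene lists had already been seen there.

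The X chromosome carried far fewer peaks than any autosome, 6.08 replicated peaks per Mb against 25.9 (chromosome 3) to 64.2 (chromosome 11), and both replicates' own lists showed it, with 8.51 against 45.9 to 114 and 8.28 against 38.1 to 93.2. Low gene density was excluded as the whole cause for promoters: 47.2% of 948 X-linked genes were marked, with an upper limit of 50.4, below the lowest autosome at 56.6% (chromosome 7), and chromosome 12 has fewer genes per Mb (5.35 against 5.54) but 81.0% marked. This share is taken per gene, and gene density was not tested for the fewer distal peaks. Low CpG content around the 5′ end was also excluded as the whole cause for promoters, since CpG-matched autosomal lists lay between 58.9 and 63.4%. CpG content at other start sites was not matched. A ratio of 3 X copies for every 4 autosome copies, from equal numbers of both sexes, was excluded as the whole cause of the fewer distal peaks: X peaks numbered 0.544 per Mb at a fold of at least 6 (0.75 times 8; 95% Poisson interval 0.439 to 0.666) and 0.357 at a fold of at least 8 (0.273 to 0.458), as when a control with the same dosage cancels it, both below 0.761 on the lowest autosome (chromosome 14) at a fold of at least 8. A single active X copy per cell is a candidate explanation that stays open. X peaks reached 1.26 per Mb at a fold of at least 4 (0.5 times 8; 1.09 to 1.44), a cut that applies only if fold over control scales fully with active copies. The prediction as written, that they would reach 0.761, was met, but it rests on that scaling, which was not tested. The median promoter fold on the X (9.78 against 13.7 to 15.9) was 0.616 to 0.715 times the autosomal medians. A factor of 0.5 would hold only if X dosage does not lower the control, whose X coverage was not analysed. A control with fewer X copies would raise the factor, so this ratio does not decide the question.

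Promoter CpG content, measured around each gene's 5′ end, was weighed for the promoter calls. A peak at any annotated start site counted as a promoter peak, and CpG content at other start sites was not matched. CpG content around the 5′ end was excluded as the whole cause for 4 lists: progenitor, neurogenic, post-mitotic, and crest and mesenchyme. Their largest adjusted p against CpG-matched lists was 0.0248. It was also excluded for Hox genes of groups 5 to 13, which are CpG-rich: matched lists had at least 72.7% (groups 5 to 8) and 81.2% (groups 9 to 13) of genes marked in the middle 95% of draws, against 0. For hindbrain neuron factors it remains a candidate explanation, as 88% were marked within a matched range of 72 to 92% (adjusted p 0.793). For the other 5 lists (hindbrain and isthmus, floor plate, roof plate, cell cycle and housekeeping) it stays open, as the matched range reached 100% and the smallest adjusted p of 0.206 decides nothing. Apart from other tissues in the sample, weighed next for the mesenchyme genes, no biological explanation of these promoter calls was tested, since the series has no second tissue.

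All 24 crest and mesenchyme genes had promoter peaks in a sample labelled hindbrain. A general admixture of embryonic tissues stays open: the 49 blood, muscle and liver genes together were marked at 32.7%, within their CpG-matched range (30.6 to 55.1%, p 0.0890), a difference of -10.3 percentage points against 27.1 for mesenchyme, but blood (38.9% against 30.5%) and endothelium (87.5% against 65.9%) lay above their matched lists and muscle and liver below. Mesenchymal cells in the dissected tissue may contribute, which also stays open: in each replicate's list the mesenchyme genes had more distal peaks than lists matched on gene density and promoter peaks (24.2 against 16.9 and 19.4 against 13.6), with adjusted p of 0.177 and 0.156. As written, the test would have excluded such cells when neither replicate was called, but both means lay above their matched lists, and a missed threshold excludes nothing. Among the most abundant mesenchymal products, Col1a1 had a promoter fold of 4.96, Col1a2 7.83 and Col3a1 4.03, and how many of the 24 genes hindbrain cells themselves mark is not given in the sources used here.

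Among 25 gene families grouped by symbol, 5 had more promoter peaks than other genes and 5 fewer by Fisher's exact test, and 7 of the 20 tested were enriched in top domains and 1 depleted. Against CpG-matched lists 3 families had more promoter peaks and 4 fewer. Sox genes, many of them regulators of neural fate, were marked at 19 of 19 (adjusted p 0.00235; 0.223 against CpG-matched lists), and 11 of them lay in top domains (1.34e-05), led by Sox11 at a fold of 36.6 (23.9 and 40.2) and Sox4 at 34.99 (28.2 and 34.4). The ephrins, which guide cells and axons at segment borders, had 7 of 8 genes in top domains (1.34e-05), with Efna5 at 27.9 (20.5 and 33.97) the highest and Efna3 the exception. Zic genes had 4 of 5 in top domains (0.00260), Irx genes 4 of 6 (0.00594), Pax genes 5 of 6 marked genes (0.000566), and Meis and Pbx genes 5 of 7 (0.00135). These 5 Pax genes and several of the Sox, Zic, Irx, and Meis and Pbx genes also belong to the gene lists. The domain results of these families therefore partly repeat those of the lists. Neighbouring genes of a family can also share a domain and are not independent in the test. Zic1 and Zic4, which overlap on chromosome 9, are such neighbours. All 4 Pou3f genes and all 4 Nfi genes lay in top domains, too few for a test, with Pou3f3 at 31.7 (27.1 and 32.7) and Nfib at 27.97 (22.0 and 29.8). Semaphorins were marked at 20 of 20 (0.0196 against CpG-matched lists), with Sema4c at 31.2 (27.04 and 39.9), and collagens at 38 of 44 (0.00500 against CpG-matched lists). Zinc finger genes named Zfp were marked at 314 of 365 (86.0%), but 19 of these 314 (6.05%) lay in top domains, against 11.04% of other genes (0.00962). Ribosomal protein genes were marked at 79 of 82, and keratins at 12 of 49, keratin-associated genes at 3 of 57, interleukins at 9 of 30, vomeronasal receptors at 1 of 331 and defensins at 0 of 64, the ribosomal and interleukin calls ending against CpG-matched lists (0.266 and 0.481).

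For non-coding genes away from protein-coding starts, only distal peaks were counted, as a wide peak can also reach a protein-coding promoter. Such peaks lay at starts of 167 of 414 processed transcript genes (40.3%), 431 of 1653 antisense genes (26.1%), 1200 of 5367 lincRNA genes (22.4%), 213 of 1733 microRNA genes (12.3%), 77 of 1273 small nuclear RNA genes (6.05%), 274 of 9635 processed pseudogenes (2.84%) and 18 of 2583 unprocessed pseudogenes (0.697%). After the lincRNA genes among the strongest distal peaks, the next folds were 35.7 (28.7 and 36.3) at Gm12974 on chromosome 4 and 34.8 (27.2 and 36.7) at C130071C03Rik, on chromosome 13 from 83721381 to 83884194, and Gm26803, which share a peak. Among microRNA genes, Mirlet7i on chromosome 10 reached 35.6 (30.1 and 40.03), Mir3089 on chromosome 2 35.1 (28.9 and 37.3) and Mir124a-2 on chromosome 3 33.4 (26.6 and 42.2). Genes can share a peak, as Mir17, Mir18, Mir19a and Mir17hg did, so these are counts of genes and not of separate peaks.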
